A study of Mus musculus with 30 samples.

How the data were processed

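F4/80-positive macrophages had been sorted from bone marrow and spleen, RNA was extracted with Trizol and labelled as biotin cRNA, and each sample was hybridised to 1 bead array, per the labels' protocols. The deposited non-normalised table gives the authors' probe intensity on a linear scale and a detection p-value for each of 45281 probes and 30 arrays. A second deposited table holds the authors' log2 values, with Partek named in the submitters' processing notes and no version; its normalisation is not given in the sources used here. Each column of the log2 table had a median of 6.41 and correlated at 0.99 to 0.997 with the log2 intensity of the same array. Slide took 0.197% of the within-group variance of a typical probe in the authors' log2 values, against 24.7% in the values used here and 21.8% with slides permuted, so the authors' values carry an adjustment for slide that no label states. Scale and direction were settled by the comparison, and centring of the authors' values remains unknown. Fits on the authors' values held no slide term, so counts of called genes from them may be too high.

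Intensities were corrected for background and quantile normalised with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16 and negative-control statistics inferred from the detection p-values. Probes detected at p under 0.05 on at least 3 arrays were kept, 23515 in all. The platform annotation listed 34885 probes with 1 symbol, 18 with several and 10378 with none; 34807 of them were matched by gene ID to a RefSeq table of assembly GRCm38.p6 for the current symbol, and probes with several symbols were given none. For each gene the kept probe with the highest mean was used, which left 11937 genes. Raw median intensity was 76.5 to 96.8, and 16492 to 18567 probes were detected per array. The number of arrays limits the precision. Where no array of a group detected a probe, a fold is given as a lower bound against the lowest detected level on each array.

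A model with the 8 groups was fitted with limma (lmFit, eBayes), so all groups share 1 estimate of the spread, and 15 contrasts were tested with Benjamini-Hochberg adjustment at 0.05. The 26 gene lists, the rule for named genes, the contrasts and most alternatives were fixed before the data were examined. The rule names Mif and Adgre1 always, and among called genes detected on most arrays of the brighter group the largest changes in each direction, up to 12 per direction for leukaemia over both genotypes and for tissue, 8 for Mif and 3 for the rest; list members are those called with the smallest p, or otherwise the 2 with the smallest p as values. Genes of the text outside the rule were chosen after their values were seen. Lists were tested with camera, with the preset correlation of 0.01 and with an estimated one, and list means per array by exact permutation of group labels within genotype where both genotypes enter; the difference between tissues used 100000 random permutations. No array was left out of the main fits, and no 2 arrays held identical values, the highest correlation being 0.994.

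The fit was tested on simulated data for 7 of the contrasts, with 200 of 11937 genes changed. For leukaemia in spleen over both genotypes 78% of 2-fold and 96% of 4-fold changes were recovered with 13 false calls, and for Mif loss in leukaemic marrow 78% and 93% with 9. The simulated values were independent between genes and had no structure between arrays.

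Alternatives were the authors' log2 values, no background correction, scaling to the 75th percentile, no filter, a strict filter (p under 0.01 on at least 15 arrays), slide as a fixed or random block, replicate numbers as a block, fits on the compared groups alone, array weights, all kept probes, the 1 slide with 3 leukaemic marrow arrays of each genotype, and leaving out each array in turn. After seeing the data, 3 fits were added: without KO-l-SP replicate 2 and WT-nl-SP replicate 1, with neutrophil and erythroid list means as covariates, and with the Xist value as a covariate; permutation of list means was also added then. The covariate fits were not read for the lists or genes the covariates are made of. A further fit that also held Casp9 as a covariate was dropped before its results were read, because Casp9 is itself called for Mif. The test of the tissue label of KO-l-SP replicate 2 was made stricter, with a 95% prediction bound of the marrow arrays, after its value had been seen.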

Results

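Gene expression was measured in F4/80-positive macrophages sorted from the bone marrow or the spleen of Eµ-TCL1 transgenic mice, a mouse model of chronic lymphocytic leukaemia in which B cells carry the human TCL1 oncogene. The mice either had or lacked Mif, the gene of macrophage migration inhibitory factor, a cytokine that signals through Cd74, and were taken with (l) or without (nl) leukaemia. The 30 bead arrays fell into 8 groups. In bone marrow (BM) there were 6 leukaemic and 3 non-leukaemic knockout (KO) arrays and 5 leukaemic and 3 non-leukaemic wild-type (WT) arrays. In spleen (SP) there were 4 leukaemic and 3 non-leukaemic knockout arrays and 3 arrays of each wild-type group. Between 36.4% and 41% of the 45281 probes were detected on an array, and 11937 genes were tested. The labels give ages of 2 to 5 months for the leukaemic and 10 to 15 months for the non-leukaemic mice, so age changes together with leukaemia in every leukaemia comparison. Leukaemia develops with age in this model, so whether the labels give the 2 age ranges in the right order is not known. The labels do not say which arrays share an animal, so p-values measure the spread between these arrays, and the number of arrays limits the precision.

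Mif separated the genotypes on every array. Its normalised log2 intensity was 11.41 ± 0.54 (SD, n = 5) in leukaemic wild-type marrow and 4.32 ± 0.12 (SD, n = 6) in leukaemic knockout marrow, and 11.98 ± 0.36 (SD, n = 3) against 4.62 ± 0.47 (SD, n = 4) in leukaemic spleen. The log2 difference between knockout and wild type was -7.09 in leukaemic marrow, -7.37 in leukaemic spleen, -6.73 in non-leukaemic marrow and -6.59 in non-leukaemic spleen, with limma adjusted p from 2.5e-15 to 1.3e-11. In non-leukaemic marrow no knockout array detected Mif, and the level there was at least 95.2-fold lower. Adgre1, the gene of the F4/80 antigen used for the sort, passed the threshold in none of the 15 comparisons. Its level was 9.98 ± 0.16 (SD, n = 3) in non-leukaemic and 8.93 ± 1.2 (SD, n = 3) in leukaemic wild-type spleen.

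**Figure D1:**
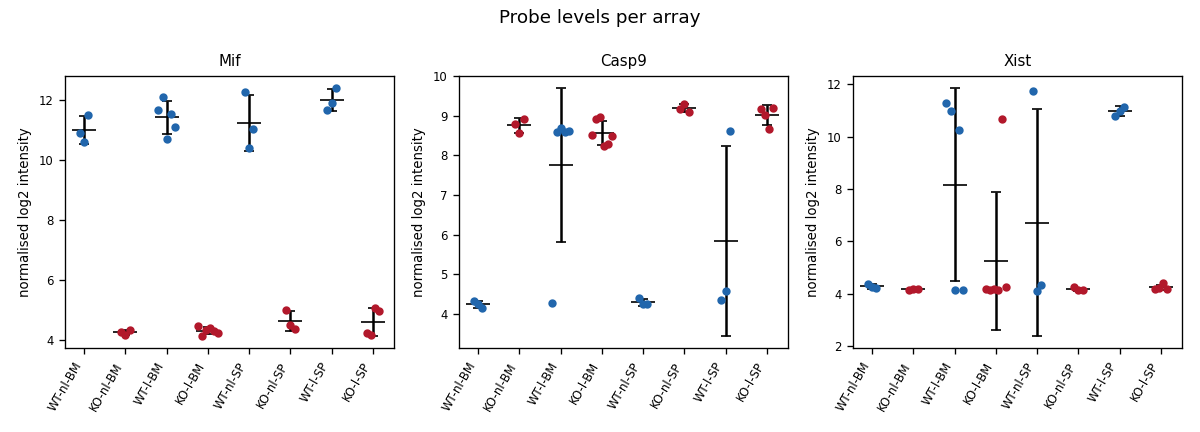
Normalised log2 intensity (vertical axis) of Mif, Casp9 and Xist on each array, by group (horizontal axis); points are arrays, blue for Mif wild type and red for knockout, and bars are the group mean and SD. Mif lies above 10 on all wild-type and below 6 on all knockout arrays, while Casp9 takes separate levels within both leukaemic wild-type groups and Xist within leukaemic marrow of both genotypes and non-leukaemic wild-type spleen.

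The question behind the leukaemia comparison was how macrophages change while the disease is present, and the series title names a gain of proliferative capacity. In spleen, the mean of both genotypes showed cell cycle genes at higher levels with leukaemia. All 36 measured genes of the mitosis list lay higher, by 1.05 on the log2 scale on average, and so did all 40 DNA replication genes, by 0.98. Examples were Kif2c, a mitotic kinesin, at +1.56 ± 0.41 (SE), Cenpa, a centromere histone, at +1.39 ± 0.36, Uhrf1, which copies DNA methylation at replication forks, at +2.08 ± 0.54, and Pold1, the catalytic subunit of DNA polymerase delta, at +1.15 ± 0.29. No member of either list passed the threshold over all genes tested, while 27 mitosis and 32 DNA replication genes did when adjusted over the list alone. Both lists were called by camera with its preset correlation, at adjusted p = 1.2e-20 and adjusted p = 3.7e-24, and neither with an estimated correlation, where adjusted p = 0.29 for both. The exact permutation test of the list means within genotype, two-sided over 700 arrangements, gave p = 0.054 for mitosis and p = 0.053 for DNA replication, each with an adjusted p = 0.28 over the 26 lists. The list mean of mitosis was -0.16 ± 0.85 (SD, n = 3) in leukaemic and -1.56 ± 0.58 (SD, n = 3) in non-leukaemic wild-type spleen, and -0.38 ± 0.73 (SD, n = 4) against -1.07 ± 1.1 (SD, n = 3) in knockout spleen. For the 76 genes of both lists together the exact p was 0.2 in wild-type spleen, where 3 arrays against 3 cannot go below 0.1, and 0.429 in knockout spleen.

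Markers of other cells moved with the cell cycle genes in leukaemic spleen. Of the 25 erythroid genes 24 lay higher, by 1.35 on average and by 0.83 without KO-nl-SP replicate 5, with Klf1, an erythroid transcription factor, at +2.21 ± 0.80 (SE) and Car1 at +2.52 ± 0.90. Of the 22 neutrophil genes 21 lay higher, by 0.79 on average and by -0.03 without WT-l-SP replicate 3. Mpo, the myeloperoxidase of neutrophil precursors, was at +2.59 ± 0.79 and the granule protease Ctsg at +2 ± 0.67. In knockout spleen the neutrophil list mean was -0.77 with and -0.76 without leukaemia. T and NK cell genes were higher by 0.55 and megakaryocyte genes by 0.38, whereas the shift was -0.57 for the macrophage identity list and -0.24 for the lysosome list. Single arrays carried part of these: the macrophage identity shift was -0.34 without WT-nl-SP replicate 1. T and NK cell genes were no longer called, at 0.21, 0.26, 0.3 and 0.33, without WT-l-SP replicate 3, WT-nl-SP replicate 1, KO-nl-SP replicate 6 or KO-l-SP replicate 3 in turn, nor lysosome genes, at -0.25, -0.18 and -0.17, without KO-nl-SP replicate 6, WT-l-SP replicate 3 or WT-nl-SP replicate 1. Mertk, a receptor for apoptotic cells, stood at -1.34 ± 0.39, the marginal-zone lectin Siglec1 at -0.70 ± 0.17 and Hmox1, the haem-degrading enzyme, at -1.53 ± 0.40. Camera with the preset correlation called all of these lists, and with an estimated correlation none, where adjusted p = 0.63 for erythroid and lysosome genes, 0.7 for neutrophil and T and NK cell genes, and 0.29 for megakaryocyte and macrophage identity genes. The joint mean of the 76 cell cycle genes was higher by 1.01 ± 0.32 (SE), and by 0.507 ± 0.25 with the erythroid list mean of each array as a covariate. With both erythroid and neutrophil list means as covariates, added after seeing the data, mitosis shifted by 0.43 and DNA replication by 0.42. With slide as a block the mitosis shift was 1.41 and the DNA replication shift 1.3. The leukaemic and non-leukaemic knockout spleen groups shared no slide. On the 1 slide with both wild-type spleen groups, the leukaemic array exceeded the non-leukaemic array by 1.56 for mitosis and 1.43 for DNA replication. That is 1 array against 1, and the leukaemic one, WT-l-SP replicate 3, correlated best with a marrow array and had the highest mitosis mean of its group, 0.64.

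**Figure D2:**
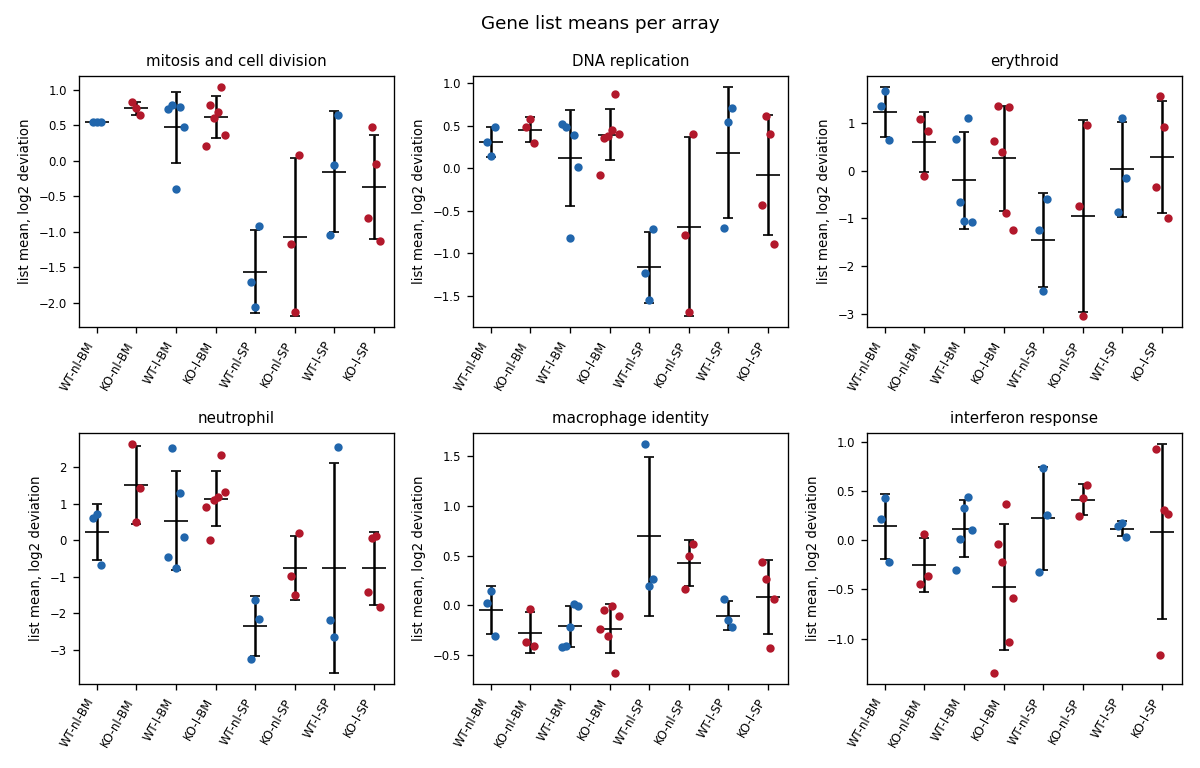
Mean log2 deviation of 6 fixed gene lists (vertical axis) on each array, by group (horizontal axis); points are arrays, blue for Mif wild type and red for knockout, and bars are the group mean and SD. Mitosis, DNA replication and erythroid means are lowest in non-leukaemic spleen, and the arrays within the spleen groups spread widely.

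Single genes rarely passed the threshold for leukaemia. In spleen 1 gene was called over both genotypes, Tkt, the transketolase of the pentose phosphate pathway, which rose by 0.76 ± 0.13 (SE) with adjusted p = 0.034, and 1890 genes had an unadjusted p under 0.05 where 597 are expected. In wild-type spleen 17 genes were called, 4 higher and 13 lower. Gdf3, a ligand of the TGF-beta family, rose by 2.13 ± 0.42, Hacd1 by 1.77 ± 0.36 and Col18a1, a basement membrane collagen, by 1.49 ± 0.26, the last being at least 2.49-fold higher because no non-leukaemic array detected it. Cbx7, a Polycomb protein, fell by 1.51 ± 0.30, Fut4 by 1.40 ± 0.28 and Slc25a36 by 1.24 ± 0.22. In knockout spleen limma called 0 genes, with 634 at an unadjusted p under 0.05, and 598 with the authors' values, 217 higher and 381 lower. The call counts depended on the values used and on single arrays. The authors' values carry an adjustment for slide and were fitted without a slide term, so their counts may be too high. With the authors' values, 2957 genes were called in spleen over both genotypes, 1313 higher and 1644 lower, and 1735 in wild-type spleen, 819 higher and 916 lower; without WT-l-SP replicate 1 the counts were 329 and 340, and with slide as a block they were 446 and 233. Without WT-nl-SP replicate 1 the counts were 0 and 0, without background correction 6 (1 higher and 5 lower) and 60, and with 75th percentile scaling 0 and 3 (2 higher and 1 lower). Xist, the transcript of the inactive X chromosome, was high on all leukaemic wild-type spleen arrays and on 1 of the 3 non-leukaemic ones, and 2 genes were called in wild-type spleen with its value as a covariate.

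In bone marrow the cell cycle lists were not called for leukaemia. The mean shift was -0.10 for mitosis and -0.13 for DNA replication, and camera called neither with the preset or the estimated correlation. Trib1, a pseudokinase that regulates myeloid differentiation, was the 1 called gene and rose by 1.35 ± 0.22 (SE), from 5.93 ± 0.23 (SD, n = 3) to 7.48 ± 0.33 (SD, n = 5) in wild-type and from 6.36 ± 0.77 (SD, n = 3) to 7.5 ± 0.17 (SD, n = 6) in knockout marrow, with limma adjusted p = 0.028. Genes of the early response and dissociation stress list, called early response genes here, were higher by 0.50, and by 0.33 without KO-nl-BM replicate 1. Of its 22 members 18 were positive, with Egr1, an immediate-early transcription factor, at +1.79 ± 0.61. The erythroid list shifted by -0.87, 23 of 25 members negative. Both were called by camera at adjusted p = 8.4e-05 and adjusted p = 0.0014, and neither with an estimated correlation, where adjusted p = 0.93 and adjusted p = 0.98. Limma called 0 genes in wild-type marrow and 0 in knockout marrow, with 1250 and 801 at an unadjusted p under 0.05. With array weights the counts were 1206 (489 higher and 717 lower) and 351 (202 higher and 149 lower), and without WT-l-BM replicate 1 the wild-type count was 51. That array had Casp9 at 4.28, near the non-leukaemic wild-type marrow arrays at 4.16 to 4.33. The other leukaemic wild-type marrow arrays were at 8.58 to 8.69. Without it, leukaemia in wild-type marrow and a strain variant at Casp9 cannot be told apart. With the authors' values 55 genes were called over both genotypes, 21 higher and 34 lower, and without WT-l-BM replicate 2 the count was 37. With array weights it was 2235, with 75th percentile scaling 2 (1 higher and 1 lower), and without KO-nl-BM replicate 1, without WT-nl-BM replicate 1 and with slide as a block it was 0. All 6 arrays of slide 6 were leukaemic marrow, and with slide as a block 451 genes had an unadjusted p under 0.05, against 1774 without it, where 597 are expected.

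The shift of the cell cycle lists with leukaemia was compared between the tissues directly. It was larger in spleen by 1.15 for mitosis and by 1.11 for DNA replication, and the erythroid shift was larger by 2.23. Camera called these at adjusted p = 4.3e-13, adjusted p = 2.5e-17 and adjusted p = 4.1e-12, and none with an estimated correlation, where adjusted p = 0.52 for each. The preset correlation also called macrophage identity genes at -0.51, lysosome genes at -0.26 and early response genes at -0.40, where adjusted p = 0.52, 0.52 and 0.73 with an estimated one. None of these was called without WT-nl-SP replicate 1, at -0.28, -0.18 and -0.36. By permutation of the tissue labels p = 0.14 for mitosis, 0.055 for DNA replication and 0.028 for erythroid genes, with adjusted p = 0.63 for mitosis and 0.54 for the others. For single genes limma called 0, with 1570 at an unadjusted p under 0.05, and 369 with the authors' values, 221 higher and 148 lower.

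Loss of Mif was compared within each tissue and disease state. In leukaemic marrow 5 genes were called, among them Manbal, which rose by 1.74 ± 0.32 (SE), Atrnl1, which was at least 2.02-fold higher, and Mtss1, an actin-binding protein, which fell by 1.02 ± 0.19. 1190007I07Rik, named here after its values were seen, was called in all 4 comparisons, at -1.48 in leukaemic marrow and at least 3-fold lower in leukaemic spleen, 2.46-fold in non-leukaemic marrow and 2.64-fold in non-leukaemic spleen, where no knockout array detected it. In leukaemic spleen 5 were called, all lower, with Zfp979 at -1.99 ± 0.36, Trappc2l at -0.98 ± 0.16 and Coa6 at -0.80 ± 0.15. In non-leukaemic marrow 9 were called, and Casp9, the initiator caspase of mitochondrial apoptosis, was at least 19.4-fold higher and Gpn2 rose by 2.55 ± 0.46, while the actin regulator Cap1 fell by 4.66 ± 0.88 and Zfp985 was at least 13.1-fold lower. In non-leukaemic spleen 32 were called, 17 higher and 15 lower. Casp9 was at least 27.1-fold higher there, Supt16, a histone chaperone, rose by 3.87 ± 0.82, Tmem71 by 2.52 ± 0.52, the sialyltransferase St3gal1 by 2.24 ± 0.42 and Psmb5, a proteasome subunit, by 1.84 ± 0.34, and Cap1 fell by 4.44 ± 0.88, Hap1 by 3.22 ± 0.67 and Fmr1 by 1.12 ± 0.23. Casp9 lay between 8.25 and 9.31 on all knockout arrays and between 4.16 and 4.4 on all non-leukaemic wild-type arrays, but 5 of the 8 leukaemic wild-type arrays were at 8.58 to 8.69. 2 other kept probes of Casp9 differed by 0.19 and -0.55 in non-leukaemic spleen. The other kept probe there differed by -0.65 for Supt16, 0.16 for St3gal1 and -0.06 for Hap1, unlike the called ones. For Zfp979 it differed by -2.35, close to the called probe at -2.25. Of the 37 genes other than Mif called in any of the 4 comparisons, 20 had another within 50 tested genes on the chromosome, against a median of 9 in random sets. With the authors' values the counts were 10 in leukaemic marrow, 33 in leukaemic spleen (14 higher), 35 in non-leukaemic marrow and 130 in non-leukaemic spleen (49 higher). With only the compared groups in the fit, 7 genes were called in non-leukaemic spleen and 37 in non-leukaemic marrow. Without WT-nl-SP replicate 3 the count in non-leukaemic spleen was 12. In non-leukaemic spleen the count was 331 without WT-nl-SP replicate 2, 16 without WT-nl-SP replicate 1 and 18 with Xist as a covariate, and in non-leukaemic marrow it was 1448 with array weights, 7 without background correction (1 higher and 6 lower) and 2 without KO-nl-BM replicate 1; in leukaemic spleen it was 8 with 75th percentile scaling (1 higher and 7 lower), 13 without WT-l-SP replicate 3, 22 with array weights (9 higher and 13 lower), 3 with slide as a block (1 higher and 2 lower), and 2 with the strict filter, without WT-l-SP replicate 1 and with Xist as a covariate. Genotype there goes with sex: Xist was at 10.78 to 11.15 on all leukaemic wild-type and at most 4.39 on all leukaemic knockout spleen arrays. In leukaemic marrow the count was 8 without WT-l-BM replicate 1 and 3 within the 1 slide with 3 arrays of each genotype, without background correction and with 75th percentile scaling.

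Gene lists were also compared for Mif loss. In leukaemic marrow all 35 interferon response genes lay lower in the knockout, with a mean shift of -0.59, with Oasl1 at -0.78 ± 0.27 (SE) and Dhx58 at -0.75 ± 0.30, and no member passed the threshold. Camera called the list at adjusted p = 5.4e-14 and not with an estimated correlation, where adjusted p = 0.38, and the exact permutation test of its mean gave p = 0.091 and an adjusted p = 0.9. Within the slide with 3 arrays of each genotype the shift was -0.7, and between the single arrays of another slide 0.26. Camera with the preset correlation also called DNA replication genes in leukaemic marrow, at 0.28, neutrophil genes at 0.61 and erythroid genes at 0.46, with adjusted p = 0.97 for each with an estimated correlation. Without WT-l-BM replicate 3 these shifts were 0.04, 0.28 and 0.25 and none was called. In leukaemic spleen it called 5 lists as higher in the knockout, T and NK cell genes at 0.43, MHC class II at 0.40, early response at 0.39, megakaryocyte at 0.33 and B cell genes at 0.28, and DNA replication genes at -0.26. With an estimated correlation adjusted p = 0.78 for megakaryocyte and B cell genes and 0.92 for the others. None was stable: the shift was -0.15 for T and NK cell genes without WT-l-SP replicate 1, -0.04 for MHC class II and 0.23 for early response genes without WT-l-SP replicate 3, 0.23 for megakaryocyte and 0.04 for B cell genes without KO-l-SP replicate 2, and 0.01 for DNA replication genes without KO-l-SP replicate 4. With Xist as a covariate MHC class II genes shifted by -0.91 and DNA replication genes by 0.28. The list of Mif and its receptors, which holds Mif, was called in both, at -0.71 (-0.63 and not called without KO-l-BM replicate 2) and -0.92, with adjusted p = 0.3 and adjusted p = 0.056 with an estimated correlation. In non-leukaemic marrow the neutrophil list was higher by 1.29 and the interferon list shifted by -0.39, with adjusted p = 0.53 and adjusted p = 0.63 with an estimated correlation; they were 0.74 without KO-nl-BM replicate 1 and -0.25 without WT-nl-BM replicate 2, and not called. The preset correlation also called eosinophil genes at -0.72, erythroid genes at -0.62, megakaryocyte genes at 0.41 and lysosome genes at -0.27, and none of these without WT-nl-BM replicate 2, at -0.27, -0.40, 0.44 and -0.24. With an estimated correlation adjusted p = 0.72 for erythroid genes and 0.53 for the other 3. In non-leukaemic spleen the neutrophil list was higher by 1.6 and the classical monocyte list by 1.05 in the knockout, where adjusted p = 0.8 for both with an estimated correlation, and without WT-nl-SP replicate 1 the monocyte shift was -0.17. Mitosis genes at 0.49, DNA replication genes at 0.48 and dendritic cell genes at -0.45 were called there with the preset correlation, and adjusted p = 0.8 for each with an estimated one. Without KO-nl-SP replicate 6 the first 2 were -0.09 and -0.06, and without WT-nl-SP replicate 3 the third was 0.03.

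Whether the response to leukaemia depends on Mif was tested as the difference between the genotypes. In spleen the shift of mitosis genes was 1.4 in wild-type and 0.7 in knockout mice, a difference of -0.70, and for DNA replication genes it was 1.35 and 0.61, a difference of -0.74. For neutrophil genes the difference was -1.6, but 0.05 without WT-l-SP replicate 3, and for classical monocyte genes -1.21, but 0.01 without WT-nl-SP replicate 1. Without KO-nl-SP replicate 6 the mitosis difference was -0.13 and the DNA replication difference -0.19, and neither was called; the mitosis difference was also not called without WT-l-SP replicate 3, at -0.30, or WT-nl-SP replicate 2, at -0.46. Dendritic cell genes had a difference in the other direction, 0.67, or 0.20 and not called without WT-nl-SP replicate 3. Camera called these differences with the preset correlation and none with an estimated one, where adjusted p = 0.7 for each, and by exact permutation adjusted p = 0.8 for each. In marrow the erythroid difference was 1.08 and the eosinophil difference 0.85, or 0.39 and not called without WT-nl-BM replicate 2, with adjusted p = 0.72 for both with an estimated correlation. For single genes limma called 0 in marrow and 0 in spleen, with 400 and 831 at an unadjusted p under 0.05. With array weights 23 were called in marrow, and without WT-nl-SP replicate 2 63 were called in spleen.

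Tissue was compared within each disease state. Without leukaemia, 927 genes differed between the sorted cells of spleen and marrow, 362 higher and 565 lower in spleen. Spic, the transcription factor of red pulp macrophages, rose by 3.46 ± 0.39 (SE), Asb2 by 3.93 ± 0.78, Rgs1 by 3.37 ± 0.79, the liver X receptor gene Nr1h3 by 2.77 ± 0.53, the integrin Itgad by 2.97 ± 0.78, and the transglutaminase Tgm2 by 2.75 ± 0.56. Lower in spleen were the granule genes Mpo, at -4.48 ± 0.81, Elane, at -4.27 ± 0.85, and Ctsg, at -3.83 ± 0.70, the eosinophil granule gene Prg2, at -4.31 ± 0.87, and the erythroid genes Slc4a1, at -3.78 ± 0.95, and Alas2, at -3.74 ± 0.89. Of 36 mitosis genes 30 fell, with a mean shift of -1.96, including Plk1 at -2.86 ± 0.45 and Cdk1 at -2.55 ± 0.40, and 28 of 40 DNA replication genes fell, including Cdc45 at -2.30 ± 0.40. Adjusted over the list alone the counts were 31 and 37. The mean shift was -2.42 for neutrophil genes, with 6 of 22 called, -2.1 for erythroid genes, with 11 of 25, and -1.27 for eosinophil genes. Macrophage identity genes were higher by 0.72, with Mertk at +1.58 ± 0.40, MHC class II genes by 0.89, or 0.53 without WT-nl-SP replicate 3, and early response genes by 0.96, with 8 of 22 called, among them Hspa1a at +3.47 ± 0.69 and Klf2 at +1.65 ± 0.22. Iron recycling genes at 0.36, classical monocyte genes at -0.66, dendritic cell genes at 0.47 and interferon genes at 0.37 were also called by camera with the preset correlation. They were not called, in the same order, at 0.28 and -0.06 without WT-nl-SP replicate 1, 0.24 without WT-nl-SP replicate 3 and 0.24 without WT-nl-SP replicate 2. With an estimated correlation no list was called, adjusted p = 0.19 being the smallest, for mitosis. By exact permutation of list means within genotype, 6 of the 26 lists passed, with adjusted p = 0.032 for mitosis, neutrophil, macrophage identity and early response genes and 0.043 for DNA replication and eosinophil genes. With the authors' values 2754 genes were called, 1405 higher and 1349 lower. With array weights 2126 were called, and without KO-nl-SP replicate 5 527. With neutrophil and erythroid list means as covariates, an alternative chosen after seeing the data, 16 genes were called. Neutrophil and erythroid cells in the sort may therefore account for part of the 927 genes. Both list means shifted with tissue, so the covariate fit cannot tell such cells apart from a change in macrophages.

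With leukaemia 800 genes differed between the tissues, 430 higher and 370 lower in spleen. Asb2 again was higher, by 2.94 ± 0.66 (SE), with the cyclin gene Ccnd1 at +2.68 ± 0.65, Dnase1l3 at +2.59 ± 0.53, the chemokine Ccl4 at +2.44 ± 0.45 and Il4i1, an amino acid oxidase, at +2.47 ± 0.64. Prg2 fell by 3.68 ± 0.73 and Serpinf1 fell by 2.13 ± 0.34, and the calprotectin genes S100a9 and S100a8 stood at -2.12 ± 0.61 and -1.76 ± 0.53, and fibronectin, Fn1, at -1.90 ± 0.51. The mean shift was -0.81 for mitosis genes, with 10 of 36 called, and -0.20 for DNA replication genes, or 0.02 without WT-l-SP replicate 1, with Pcna the 1 called member at -0.96 ± 0.28. MHC class II genes were higher by 0.94, with H2-Ab1 at +1.89 ± 0.54, dendritic cell genes by 0.60, with Batf3 at +1.57 ± 0.40, and T and NK cell genes by 1.11, with Cd2 at +1.59 ± 0.40. Neutrophil genes shifted by -1.6, or -2.43 without WT-l-SP replicate 3, and classical monocyte genes by -0.66, eosinophil genes by -1.01, megakaryocyte genes by 0.38 and early response genes by 0.56. With an estimated correlation adjusted p = 0.44 was the smallest of any list. By exact permutation 10 lists passed, with adjusted p = 0.0044 for classical monocyte, 0.011 for iron recycling, dendritic cell, eosinophil, megakaryocyte and early response, 0.013 for stromal, 0.027 for M1-type, 0.028 for mitosis and 0.037 for MHC class II genes. Of the genes called, 217 were shared with the comparison without leukaemia, all in the same direction, where independent lists share 13 higher and 17.5 lower. The arrays of the 2 comparisons are different ones, but 1 estimate of the spread of each gene serves both. The lists are therefore not independent, and part of the overlap can come from that. Without WT-l-SP replicate 2 the count was 208, with slide as a block 30, with array weights 1960, with 75th percentile scaling 436 and with the authors' values 1447.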

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

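Tests of neighbouring genes, of the tissue label and of erythroid genes on a single array, and counts at an unadjusted p with slide as a block, were chosen after the result was seen. An array far from the rest of its group was looked for in 300 pairs of a group with a list or named gene, and 24 were found where chance gives about 1 in 20. In leukaemic knockout marrow the eosinophil list mean of replicate 3 was 1.92 against 0 to 0.69, with Ear6 at 11.47 and Epx at 8.62, the T and NK cell mean of replicate 5 was 0.62 with Sh2d2a at 7.09 and Pigv at 4.8, the M1-type mean of replicate 4 was 0.47, and replicate 2 had Tmem71 at 6.85 and Tppp3 at 7.24. In leukaemic knockout spleen replicate 3 had a cholesterol list mean of -0.25, Manbal at 7.59 and Spic at 5.89, and replicate 1 had Cbx7 at 5.59 and Rgs1 at 8.51. In leukaemic wild-type marrow the mitosis mean of replicate 3 was -0.4 against 0.47 to 0.78, with Slc25a36 at 7.34 and Prg2 at 8.44, the plasma cell mean of replicate 4 was 0.87 with Dnase1l3 at 4.81, replicate 2 had Col18a1 at 4.41, and replicate 1 had Casp9 at 4.28, Gpn2 at 6.17, Supt16 at 4.34 and Srpr at 5.36.

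Cell cycle genes lay higher in leukaemic spleen together with erythroid genes and, in wild type, neutrophil genes. The neutrophil list mean was -0.77 in leukaemic and -0.76 in non-leukaemic knockout spleen, and -0.76 and -2.36 in wild-type spleen. The joint mean of the 76 genes was higher by 1.01 ± 0.32 (SE), and with slide as a fixed term by 1.35 ± 0.39. The leukaemic and non-leukaemic knockout spleen groups shared no slide, and the wild-type ones 1 slide with 1 array each. The slide term therefore rests largely on other groups, and slides stay open as a cause. With the erythroid list mean as a covariate the shift was 0.507 ± 0.25, 0.5 of its size, and with the neutrophil list mean 0.815 ± 0.28. With both as covariates, a fit added after seeing the data, the mitosis list shifted by 0.43 and the DNA replication list by 0.42. Precursor cells of either kind in the sort therefore cannot be told apart from dividing macrophages, because the spread is too wide for either single test to decide. The F4/80 gate would remove such cells if it were complete, and yet the abundant erythroid gene Slc4a1 was at 12.14 ± 1.3 and 9.47 ± 4.1 (SD) in leukaemic and non-leukaemic knockout spleen and Mpo at 10.49 ± 1.5 and 8.55 ± 1.6; 0 of the 76 genes are in either list. Leukaemia and age, which the design names together, stay untested against each other.

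Among genes other than Mif that differed with its loss, many lay next to one another. Of 37 such genes 20 had another within 50 tested genes in the order of assembly GRCm38.p6. The median was 9 in 10000 random sets, of which a share of 0.0022 reached 20. A single run held 5 of the 20 (Casp9, 4930455G09Rik, Zfp985, Zfp979 and Zfp933). Of the 37 genes 0 lay in the window of Mif, and 2, Pex3 and 1190007I07Rik, lay on its chromosome. For 19 other kept probes of 15 of the genes, the median ratio of their difference to that of the called probe was 0.17, with quartiles of 0.055 and 0.62. Each other probe had the lower mean, and the called probe was picked for its call. A ratio under 1 can therefore arise without a variant under the probe. Given the neighbouring genes, strain variants carried along in neighbouring stretches may account for part of these differences. Whether some lie under a probe stays open. WT-l-BM replicates 2 to 5 and WT-l-SP replicate 3 had Mif at 10.7 to 12.38. On these arrays Casp9 was at 8.58 to 8.69, Gpn2 at 8.28 to 8.41 and Supt16 at 7.9 to 8.48. Psmb5 was at 7.25 to 7.65 and Srpr at 6.98 to 7.63. All lay within the range of the knockout arrays, which argues against loss of Mif as the cause for these genes. WT-l-BM replicates 3 to 5 share slide 6. On them St3gal1 (6.26 to 6.37), Cap1 (8.65 to 9.08) and Zfp979 (4.33 to 4.58) also lay within that range. Tmem71 was at 6.92 to 7.57, against 6.55 to 7.56 on the knockout arrays, and Zfp985 at 4.12 to 4.24, against 4.13 to 4.26. These arrays argue against loss of Mif for these genes too, though the other wild-type arrays lay outside the knockout range. 1190007I07Rik separated the genotypes on every array but lay on the chromosome of Mif, so a strain variant linked to Mif stays open. For the remaining genes an effect of Mif was not tested apart from strain variants.

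KO-l-SP replicate 2 correlated best with a marrow array, KO-l-BM replicate 1, at 0.98 across genes, against a mean of 0.943 with its own group, and 2 other spleen arrays did the same, WT-l-SP replicate 3 at 0.984 and KO-nl-SP replicate 6 at 0.979. Genes higher in non-leukaemic spleen had a median deviation of -0.05 on it, between the marrow arrays of its genotype (-0.51 to -0.15) and the other spleen arrays (0.08 to 0.5), so a wrong tissue label cannot be told apart from a mixed sample because the value lies within the prediction bound of 0.08 of 6 marrow arrays. Against a marrow label, 121 of those 362 genes lay above all 6 marrow arrays, where a marrow array lay above the other 5 for 18 to 111, Spic was at 7.4 against 4.32 to 5.38 and Hap1 at 6.04 against 4.18 to 4.68, but the count lies within its prediction bound of 143 and both genes were picked after their values were seen. Of 25 erythroid genes 22 were above the other 3 arrays, with a mean difference of 1.72, and erythroid cells in the sort are a candidate explanation. Mitosis genes also differed by 1.14, DNA replication genes by 0.93, neutrophil genes by 1.11 and plasma cell genes by 1.06. B cell genes differed by 0.97, T and NK cell genes by -0.94 and interferon genes by -1.68. Whether erythroid cells alone could bring these differences was not tested, and marrow material stays open.

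Other splits of the same arrays were tried for each comparison, and the shares were not adjusted for the number of comparisons. Taken singly, chance can be excluded at 0.05 for tissue without leukaemia, where 1 of 100 splits (the real one) reached 927 genes and the highest other 369. The same holds for tissue with leukaemia, with 1 of 100 at 800 against 64. By genes at an unadjusted p under 0.05 the share was 1 of 100 for leukaemia in marrow (1774 against 1531). It was 4 of 100 in spleen (1890 against 2164) and 2 of 56 in wild-type marrow (1250 against 1894). Limma called at most 1 gene in each of these leukaemia comparisons, and in spleen and wild-type marrow another split exceeded the real count. Because the shares are unadjusted, they do not exclude chance for these leukaemia counts. The splits ignore slide, and the one with 1894 puts the 3 arrays of slide 6 on one side. With slide as a block the marrow counts were 451 over both genotypes, 563 in wild type and 241 in knockout, under the 597 expected. Slide therefore stays open as a cause of the marrow counts. The spleen count was 2665, but the knockout spleen groups shared no slide, so slide stays open there too. For tissue with leukaemia 1431 genes had an unadjusted p under 0.05 with slide as a block, against 2833 without it, so slide may account for part of that count. Chance cannot be excluded for knockout marrow (13 of 84, 801 against 1670) or knockout spleen (17 of 35, 634 against 2239). Nor can it for leukaemia by tissue (6 of 100, 1570 against 2620), leukaemia by Mif in marrow (44 of 100, 400 against 1222) or in spleen (51 of 100, 831 against 2400). By called genes it cannot for Mif in leukaemic marrow (8 of 100, 5 against 341) or in leukaemic spleen (5 of 35, 5 against 142). These high counts point to a structure of the arrays other than genotype: the split of the leukaemic marrow arrays into the 6 of slide 6 and the 5 others gave 1796 genes at an unadjusted p under 0.05, against 346 for genotype. With 10 splits no share under 0.05 can be had for wild-type spleen (2 of 10, 17 against 22), Mif in non-leukaemic marrow (1 of 10, 9 against 0) or Mif in non-leukaemic spleen (1 of 10, 32 against 16).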

How the results depend on the processing

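The fits without 2 spleen arrays and with covariates, and permutation of list means, were chosen after the data were seen; the other alternatives were planned. The mitosis and DNA replication lists stayed higher in leukaemic spleen and past the camera threshold with its preset correlation in every other fit run on them, with shifts from 0.43 and 0.42 with the covariates to 1.41 and 1.3 with slide as a fixed block, and slide as a random block moved no count by over 1.5 times. Counts from the authors' values may be too high, because slide had been taken out of them and the fits held no slide term. Single genes passing the threshold for leukaemia depended on the values and on single arrays. The cause was not tested for any of these changes, except that fewer arrays or genes entered some fits. Probes near background limit small changes. With 75th percentile scaling the median log2 difference of all genes was -0.128 for leukaemia in wild-type marrow, against -0.027 in the main fit. It was -0.11 against -0.011 for Mif in non-leukaemic marrow and 0.111 against 0.006 for leukaemia by Mif in marrow.

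With the authors' log2 values the number of called genes was 55 for leukaemia in marrow, 2957 for leukaemia in spleen, 15 for leukaemia in wild-type marrow, 1735 for leukaemia in wild-type spleen, 598 for leukaemia in knockout spleen, 10 for Mif in leukaemic marrow, 33 for Mif in leukaemic spleen, 35 for Mif in non-leukaemic marrow, 130 for Mif in non-leukaemic spleen, 2754 for tissue without leukaemia, 1447 for tissue with leukaemia and 369 for leukaemia by tissue. Without background correction the number of called genes was 0 for leukaemia in marrow, 6 for leukaemia in spleen, 60 for leukaemia in wild-type spleen and 3 for Mif in leukaemic marrow. With 75th percentile scaling the number of called genes was 2 for leukaemia in marrow, 0 for leukaemia in spleen, 3 for leukaemia in wild-type spleen, 3 for Mif in leukaemic marrow, 8 for Mif in leukaemic spleen and 436 for tissue with leukaemia. Without the filter on dim probes the number of called genes was 0 for leukaemia in marrow, 8 for leukaemia in wild-type marrow, 3 for leukaemia in wild-type spleen, 3 for Mif in leukaemic marrow and 3 for Mif in leukaemic spleen. With slide as a fixed block the number of called genes was 0 for leukaemia in marrow, 446 for leukaemia in spleen, 233 for leukaemia in wild-type spleen, 3 for Mif in leukaemic spleen, 5 for Mif in non-leukaemic marrow, 12 for Mif in non-leukaemic spleen and 30 for tissue with leukaemia. With array weights the number of called genes was 2235 for leukaemia in marrow, 0 for leukaemia in spleen, 1206 for leukaemia in wild-type marrow, 82 for leukaemia in wild-type spleen, 351 for leukaemia in knockout marrow, 22 for Mif in leukaemic spleen, 1448 for Mif in non-leukaemic marrow, 53 for Mif in non-leukaemic spleen, 2126 for tissue without leukaemia, 1960 for tissue with leukaemia and 23 for leukaemia by Mif in marrow. With only the compared groups in the fit the number of called genes was 2 for leukaemia in marrow, 0 for leukaemia in spleen, 1 for leukaemia in wild-type spleen, 3 for Mif in leukaemic marrow, 9 for Mif in leukaemic spleen, 37 for Mif in non-leukaemic marrow and 7 for Mif in non-leukaemic spleen. Over all kept probes the number of called genes was 6 for leukaemia in marrow, 0 for leukaemia in spleen, 7 for leukaemia in wild-type marrow, 7 for leukaemia in wild-type spleen, 13 for Mif in leukaemic marrow, 12 for Mif in leukaemic spleen, 21 for Mif in non-leukaemic marrow, 57 for Mif in non-leukaemic spleen and 1315 for tissue with leukaemia. Without the 2 spleen arrays that stand apart the number of called genes was 0 for leukaemia in marrow, 0 for leukaemia in spleen, 1 for leukaemia in wild-type marrow, 3 for leukaemia in wild-type spleen, 13 for Mif in non-leukaemic spleen, 1399 for tissue with leukaemia and 1 for leukaemia by Mif in spleen. The log2 shift was then -0.48 for the classical monocyte list for leukaemia in wild-type spleen, 0.09 for the interferon response list for leukaemia in knockout spleen and -0.17 for the classical monocyte list for Mif in non-leukaemic spleen. With neutrophil and erythroid list means as covariates the number of called genes was 0 for leukaemia in marrow, 0 for leukaemia in spleen, 1 for leukaemia in wild-type spleen, 18 for Mif in leukaemic spleen, 54 for Mif in non-leukaemic spleen and 16 for tissue without leukaemia. The log2 shift was then 0.2 for the mitosis and cell division list for leukaemia in marrow, 0.15 for the DNA replication list for leukaemia in marrow, -0.01 for the mitosis and cell division list for Mif in non-leukaemic spleen and 0.03 for the DNA replication list for tissue with leukaemia. With the Xist value as a covariate the number of called genes was 0 for leukaemia in marrow, 0 for leukaemia in spleen, 2 for leukaemia in wild-type spleen, 2 for Mif in leukaemic spleen and 18 for Mif in non-leukaemic spleen. The log2 shift was then -0.33 for the DNA replication list for leukaemia in marrow, 0.28 for the DNA replication list for Mif in leukaemic spleen and -0.91 for the MHC class II presentation list for Mif in leukaemic spleen. With an estimated correlation the shifts of the mitosis and DNA replication lists for leukaemia in spleen stayed at 1.05 and 0.98 but were no longer called. With the strict filter the number of called genes was 0 for leukaemia in wild-type spleen, 3 for Mif in leukaemic marrow, 2 for Mif in leukaemic spleen and 5 for Mif in non-leukaemic marrow. Within the 1 slide with 3 arrays of each group the number of called genes was 3 for Mif in leukaemic marrow.

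Leaving out 1 array at a time, the number of called genes ran from 0 to 37 for leukaemia in marrow, 0 to 329 for leukaemia in spleen, 0 to 51 for leukaemia in wild-type marrow, 0 to 340 for leukaemia in wild-type spleen, 0 to 0 for leukaemia in knockout marrow, 0 to 3 for leukaemia in knockout spleen, 3 to 8 for Mif in leukaemic marrow, 2 to 13 for Mif in leukaemic spleen, 2 to 5 for Mif in non-leukaemic marrow, 12 to 331 for Mif in non-leukaemic spleen, 527 to 1202 for tissue without leukaemia, 208 to 1157 for tissue with leukaemia, 0 to 0 for leukaemia by tissue, 0 to 5 for leukaemia by Mif in marrow and 0 to 63 for leukaemia by Mif in spleen. The log2 shift ran from -0.14 to 0.01 for the mitosis and cell division list for leukaemia in marrow, -0.18 to -0.01 for the DNA replication list for leukaemia in marrow, 0.78 to 1.34 for the mitosis and cell division list for leukaemia in spleen and 0.73 to 1.25 for the DNA replication list for leukaemia in spleen. Shifts that changed sign in such a fit ran from -0.03 to 1.27 for the neutrophil list for leukaemia in spleen, -0.48 to 1.43 for the classical monocyte list for leukaemia in wild-type spleen, -0.06 to 2.54 for the neutrophil list for leukaemia in wild-type spleen, -0.61 to 0.09 for the interferon response list for leukaemia in knockout spleen, -0.7 to 0.01 for the DNA replication list for Mif in leukaemic spleen, -0.15 to 1.12 for the T and NK cell list for Mif in leukaemic spleen, -0.04 to 0.82 for the MHC class II presentation list for Mif in leukaemic spleen, -0.09 to 1.02 for the mitosis and cell division list for Mif in non-leukaemic spleen, -0.06 to 0.99 for the DNA replication list for Mif in non-leukaemic spleen, -0.17 to 1.74 for the classical monocyte list for Mif in non-leukaemic spleen, -0.72 to 0.03 for the dendritic cell list for Mif in non-leukaemic spleen, -0.34 to 0.02 for the DNA replication list for tissue with leukaemia, -1.9 to 0.01 for the classical monocyte list for leukaemia by Mif in spleen and -2.55 to 0.05 for the neutrophil list for leukaemia by Mif in spleen. The arrays whose absence moved a count by over 1.5 times were these, each left out alone. For leukaemia in marrow the count was 0 without any 1 of KO-l-BM replicate 1, 4 or 6, KO-nl-BM replicate 1 or 2, WT-l-BM replicate 3 or 4, WT-nl-BM replicate 1, 2 or 3, 2 without KO-l-BM replicate 2, 24 without WT-l-BM replicate 1 and 37 without WT-l-BM replicate 2. For leukaemia in spleen the count was 26 without KO-l-SP replicate 1, 0 without any 1 of KO-l-SP replicate 2 or 3, KO-nl-SP replicate 4 or 5, WT-nl-SP replicate 1, 248 without KO-nl-SP replicate 6, 329 without WT-l-SP replicate 1, 32 without WT-nl-SP replicate 2 and 51 without WT-nl-SP replicate 3. For leukaemia in wild-type marrow the count was 51 without WT-l-BM replicate 1, 5 without WT-nl-BM replicate 2 and 6 without WT-nl-BM replicate 3. For leukaemia in wild-type spleen the count was 340 without WT-l-SP replicate 1, 0 without any 1 of WT-l-SP replicate 2, WT-nl-SP replicate 1, 2 without WT-l-SP replicate 3, 282 without WT-nl-SP replicate 2 and 155 without WT-nl-SP replicate 3. For leukaemia in knockout spleen the count was 3 without KO-nl-SP replicate 4. For Mif in leukaemic marrow the count was 3 without any 1 of KO-l-BM replicate 2, 3 or 4, WT-l-BM replicate 3, 4 or 5 and 8 without WT-l-BM replicate 1. For Mif in leukaemic spleen the count was 3 without KO-l-SP replicate 1, 2 without WT-l-SP replicate 1 and 13 without WT-l-SP replicate 3. For Mif in non-leukaemic marrow the count was 2 without any 1 of KO-nl-BM replicate 1, 2 or 3, WT-nl-BM replicate 1, 5 without WT-nl-BM replicate 2 and 4 without WT-nl-BM replicate 3. For Mif in non-leukaemic spleen the count was 21 without KO-nl-SP replicate 4, 19 without KO-nl-SP replicate 5, 14 without KO-nl-SP replicate 6, 16 without WT-nl-SP replicate 1, 331 without WT-nl-SP replicate 2 and 12 without WT-nl-SP replicate 3. For tissue without leukaemia the count was 572 without KO-nl-BM replicate 1, 564 without KO-nl-SP replicate 4, 527 without KO-nl-SP replicate 5, 608 without WT-nl-BM replicate 1 and 604 without WT-nl-SP replicate 1. For tissue with leukaemia the count was 525 without KO-l-BM replicate 4, 524 without KO-l-BM replicate 6, 373 without KO-l-SP replicate 3, 516 without WT-l-BM replicate 5, 508 without WT-l-SP replicate 1 and 208 without WT-l-SP replicate 2. For leukaemia by Mif in marrow the count was 5 without WT-l-BM replicate 1. For leukaemia by Mif in spleen the count was 1 without WT-l-SP replicate 3 and 63 without WT-nl-SP replicate 2.

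Replicate numbers did not pair the arrays: of 31 same-numbered pairs 10 had deviations from the group means that correlated over 0.1, from -0.5 to 0.48, and in no comparison with 3 or more pairs did every pair. With replicate number as a block the number of called genes was 0 for leukaemia in marrow, 0 for leukaemia in wild-type spleen, 1 for Mif in leukaemic marrow, 2 for Mif in leukaemic spleen, 5 for Mif in non-leukaemic marrow and 58 for tissue with leukaemia. The log2 shift was then -0.19 for the mitosis and cell division list for leukaemia in marrow, -0.24 for the DNA replication list for leukaemia in marrow and 0.01 for the DNA replication list for Mif in leukaemic spleen. No paired analysis was possible because the groups share no number for Mif in non-leukaemic spleen. It was also not run, because at least 2 shared numbers were asked for beforehand, for tissue without leukaemia and leukaemia by tissue, where KO-nl-BM and KO-nl-SP share none, or for leukaemia in spleen, leukaemia in knockout spleen and leukaemia by Mif in spleen, where the knockout groups share 1, although the wild-type groups share 3.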

Other observations

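The fit with Xist as a covariate was chosen after the result was seen. Camera called none of the lists tied to tumour-associated macrophages for leukaemia in spleen, which does not show that they were unchanged. The M2-type activation list shifted by -0.14, the M1-type list by 0.13, the list of tumour-promoting and B-cell-supporting factors by 0.04, chemokines and their receptors by 0.21, complement by -0.27, glycolysis by -0.16 and cholesterol synthesis by -0.20. Within these lists Mrc1, the mannose receptor, stood at -0.81 ± 0.40 (SE). The list of B cell and leukaemia cell genes shifted by 0.16, plasma cell genes by 0.26, stromal genes by 0.04 and the list of Mif and its receptors by 0.20. The remaining lists outside the comparisons above shifted by -0.15 (iron recycling), 0.14 (classical monocyte, from 0.74 in wild-type and -0.47 in knockout spleen), 0.12 (eosinophil), -0.06 (dendritic cell), -0.22 (interferon), -0.09 (MHC class II) and 0.10 (early response), and none was called.

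WT-nl-SP replicate 1 stood apart from the other arrays, with a mean correlation of 0.884 with all of them. Its macrophage identity mean was 1.62 and its complement mean 1.56, while classical monocyte genes were at -3.41 and neutrophil genes at -3.26. Spic was at 10.77 on it, against 8.17 and 9.02 on the other arrays of its group.

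Sex-linked transcripts differed within and between groups. Xist was between 10.26 and 11.73 on KO-l-BM replicate 5, WT-l-BM replicates 1, 2 and 4, all 3 WT-l-SP arrays and WT-nl-SP replicate 1, and at most 4.39 on the others, and the Y-linked Eif2s3y was at most 4.25 on those 8 arrays. All leukaemic wild-type spleen arrays were therefore of the first kind and all knockout spleen arrays of the other. With Xist as a covariate, an alternative chosen after seeing the data, 2 genes were called for leukaemia in wild-type spleen and 18 for Mif in non-leukaemic spleen.

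Casp9, Gpn2, Supt16, Psmb5, Srpr and Zfp985 took separate levels among the leukaemic wild-type arrays. WT-l-BM replicate 1 and WT-l-SP replicates 1 and 2 had Casp9 at 4.28, 4.35 and 4.57, near the level of the non-leukaemic wild-type arrays. The other leukaemic wild-type arrays had it at 8.58 to 8.69. Strain variants may therefore change in part with leukaemia in the wild-type comparisons, which was not tested. Zfp985 was at 4.12, 4.24 and 4.16 on WT-l-BM replicates 3, 4 and 5, which share slide 6, and at 7.18 to 7.9 on the other leukaemic wild-type arrays.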
